A study of Homo sapiens with 2 samples.

How the data were processed

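Chromatin immunoprecipitation with sequencing (ChIP-seq) of KLF7 was done in HaCaT cells, a spontaneously immortalised human keratinocyte line. The series has 2 libraries, 1 immunoprecipitate made with an antibody to the FLAG peptide tag and 1 input made without antibody. Per the labels' protocols, nuclei were sonicated, libraries were amplified over 15 PCR cycles, fragments of about 250 bp including adapters were cut from a gel, and sequencing used a HiSeq 2500. CASAVA 1.4 and the build hg18 are named in the submitters' processing notes. The aligner, the peak caller and its threshold, and the annotation tool are not given in the sources used here.

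A single table of peaks was analysed. It lists for each peak its position and width, a summit offset, a −log10 p and a −log10 q, a score, an annotation class, and the transcript assigned to it with the signed distance to that transcript's start. The −log10 p and −log10 q of each peak are the authors' own values, per the file headers, and the control and the test behind them are not stated there. The authors' score column is headed as 10 times −log10 of q, but it equals the whole part of 10 times the −log10 p in 870 of 870 rows, so it was not used as an adjusted value. Widths, summit offsets and distances are in bp, per the file headers. In a peak list such values describe single peaks of 1 library pair and were used only to describe, rank or filter peaks within the list. Peak numbers in the table run to 893, and 23 of them do not occur in the table analysed.

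The table's coordinates were taken as GRCh38, although the processing notes name hg18. All 6 unplaced scaffolds with a peak have GRCh38 names, and 371 of the 831 assigned transcripts on chromosomes share an end, within 50 bp, with a gene in the RefSeq annotation of GRCh38.p14. After moving the transcripts by 4 distances from -300000 to 100000 bp, at most 6 did. All coordinates are GRCh38, counted from 1 as in the table.

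The table gives gene identifiers without symbols, and the RefSeq annotation used here does not pair those identifiers with symbols. Genes were therefore named by position, which departs from the design set before the data were examined. A coding gene counted as having a peak when a peak met its body or the 3 kb on either side. Assigned transcripts were also matched to RefSeq genes by a shared end within 50 bp and an overlap of at least 0.5 of the transcript, which named 382 of the 870 rows. That matching was an added alternative. Without strand in the annotation, distances to coding genes were measured to the nearer of both ends. The largest gene-free stretch of a chromosome is the longest interval between consecutive annotated genes of any type. A peak inside it or within 2 Mb of it was called near it.

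Shares of peaks were given with exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. Positions relative to genes were compared with 1000 random placements of the 864 peaks on chromosomes, each on its own chromosome between position 1 and the last annotated gene end, with two-sided permutation p-values and Benjamini-Hochberg adjustment over the 8 measures of a set (7 for the sets without peaks near the stretch). Random positions can fall in assembly gaps, where no peak can be called, so placement outside the largest gene-free stretch was added as an alternative, as was leaving out both peaks and random positions within 2 Mb of that stretch. Peaks per chromosome were tested with two-sided exact binomial tests against expectations by coding gene number and by length up to the last gene end, adjusted over 24 chromosomes. The 21 gene lists were tested with two-sided Fisher's exact tests against 20033 coding genes. Of the 779 listed names, 7 did not match a gene. The random placement called 0 of 20 simulated sets without an effect and 20 of 20 with 60 peaks moved to gene ends. The list test called 1 of 100 simulated sets without an effect and 100 of 100 with 6 members added. Its simulated genes were drawn without regard to gene length. The 6 members exceed the expected count of any list in the main setting, at most 1.30, so smaller effects were not covered. The chromosome test called 3 of 100 sets without an effect and 92 of 100 with the count of chromosome 7 doubled. These simulations used 864 peaks for placements and chromosomes and 20033 genes for the lists. P-values were read as Poisson tails only in the additional observations. There, the true count and background were among the matches for 500 of 500 simulated values. Those values were drawn from the same counts and backgrounds that are searched, so the result checks the calculation only. It does not show that the deposited p-values are such tails.

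The rule for named genes, set before the data were examined, took KLF7 itself, the 15 peaks with the smallest p because no enrichment is given, the 5 gene identifiers with the most peaks, and up to 4 members with a peak from each list. An item that this rule takes is not reported here. Peaks at promoters of other coding genes, RBFOX1 and the other coding genes with several peaks, and chromosome sides were chosen after their values were seen. Alternatives were the 455 peaks at or above the median −log10 p, other windows and starting points for distances, other backgrounds and flanks for the gene lists, and sets without peaks near the gene-free stretch. A genome sequence was not used here, so a KLF motif search was not done. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.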

Results

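KLF7, a zinc-finger transcription factor of the Krüppel-like family, was mapped by ChIP-seq in HaCaT keratinocytes to find its binding sites. The antibody was to the FLAG tag, not to KLF7 itself. The series has no FLAG immunoprecipitate from cells without the tag, so background of the antibody cannot be told from binding. The immunoprecipitate and the input were 1 library each, so no value has a replicate error and no test across samples was possible. The peak list held 870 regions, 864 on chromosomes and 6 on unplaced scaffolds. The depth of both libraries is unknown, because the table gives a p-value and no read count for each peak. Peaks had a median width of 220 bp (interquartile range 215 to 271), and 413 of them (47.5%) had the smallest width of 215 bp.

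The strongest peaks lay on chromosome 4. In the authors' deposited table, the peak at chr4:50676894-50677247 had a −log10 p of 61.0, the largest of the list, and chr4:49710624-49710957 followed with 46.7. Both are distal intergenic, in a stretch without annotated genes between positions 49589729 and 51833883. The nearest coding genes are DCUN1D4, 1156637 bp from the first peak, and CWH43, 648545 bp from the second. Peaks at chr4:49711389-49711795 and chr4:51107172-51107448 in that stretch reached 24.6 and 13.2 in the authors' deposited table. For the peaks in that stretch, a pile-up of reads from repeat copies stays open, as set out in the additional observations. Another chromosome 4 peak, at chr4:189233811-189234125, had a −log10 p of 27.8 in the authors' deposited table and lay 706747 bp from FRG1, the nearest coding gene.

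The CREBBP peak was the strongest one outside chromosome 4 and the strongest in a coding gene. CREBBP encodes the CREB-binding protein, a histone acetyltransferase and coactivator. In the authors' deposited table this peak at chr16:3849274-3849594 had a −log10 p of 16.2, an adjusted p of 4.88e-11 and the class promoter within 1 kb, 727 bp from the start of the assigned transcript. That start is internal to the gene, since the peak lies 31119 bp from the nearer end of CREBBP (chr16:3725054-3880713). TAF11L7, a TAF11-like gene, was the only other coding gene among the 15 strongest peaks, with a peak at chr5:17586836-17587053 that lay 1078 bp from the gene and had an adjusted p of 0.00679 in the authors' deposited table.

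The other members of the 15 strongest were mostly far from coding genes. Chromosome 17 held 3 of them, at positions 25115367, 24751964 and 25101194, over 2 Mb from WSB1, with −log10 p of 15.5, 8.41 and 7.84 in the authors' deposited table. Peaks at chr10:42073449-42073694 and chr16:46387792-46388026 had 10.2 and 9.42 in the authors' deposited table, and their nearest coding genes were ZNF33B and SHCBP1, 500475 and 190565 bp away. The peak at chrY:11305291-11305508, at a distance of -1410 bp to the start of the pseudogene DUX4L16, had 11.2, and the peak at chrX:9405655-9406085, at the start of a transcript 57210 bp from TBL1X, had 7.42 in the authors' deposited table. The scaffold GL000225.1 held the last of the group, with 7.53 in the authors' deposited table. In all, 11 of the 15 were distal intergenic, 4 were classed as promoter, and 9 lay within 2 Mb of the largest gene-free stretch of their chromosome.

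Below these peaks the evidence per region fell steeply. The median −log10 p of the list was 3.40 (interquartile range 2.67 to 4.20) and the largest p was 0.00484 in the authors' deposited table. An adjusted p of 1 was listed for 747 peaks (85.9%), and 23 (2.64%) were under 0.05 in the authors' deposited table. These p-values belong to the peak calls of 1 library pair and carry no information on reproducibility.

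**Figure D1:**
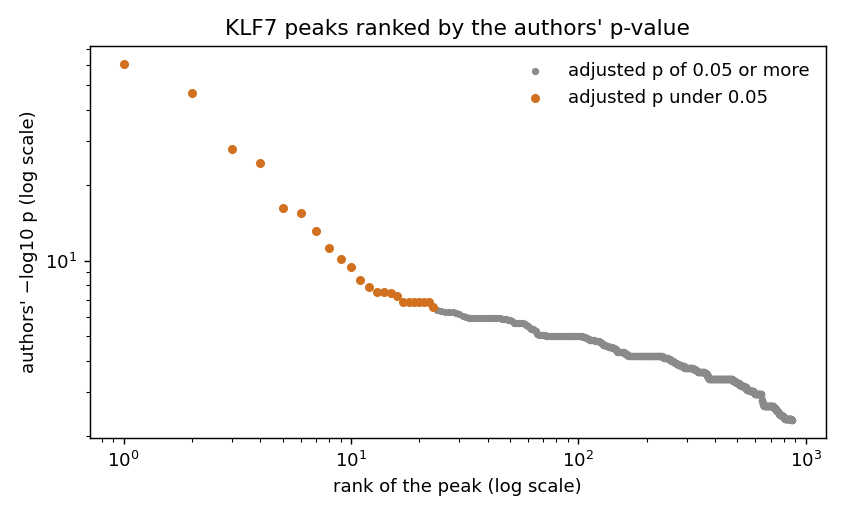
Authors' −log10 p of the 870 peaks (y axis, log scale) against their rank (x axis, log scale), with the 23 peaks of adjusted p under 0.05 in orange and the rest in grey. The values fall from 61.0 to 2.31, and 9 peaks lie above 10.

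Peaks were classed by their position relative to genes. Distal intergenic regions held 382 of the 870 peaks (43.9%, exact 95% interval 40.6 to 47.3) and introns 319 (36.7%, 33.5 to 40.0). Promoters held 137 (15.7%, 13.4 to 18.3), of which 69 lay within 1 kb of the start of the assigned transcript, 42 at 1 to 2 kb and 26 at 2 to 3 kb. Exons held 14 peaks, 3' untranslated regions 11, 5' untranslated regions 2 and downstream regions 5. Among the 23 peaks with an adjusted p under 0.05, 17 were distal intergenic (73.9%, 51.6 to 89.8), 6 were in promoters (26.1%, 10.2 to 48.4) and 0 were in introns.

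Promoter peaks within 1 kb of an assigned start and in or near a coding gene had an adjusted p of 0.166 or more in the authors' deposited table, apart from those of CREBBP and TAF11L7. Of the 69 peaks within 1 kb of an assigned start, 49 lay in or within 3 kb of a coding gene, and only those 2 of the 49 had an adjusted p under 0.05. Next in rank were ATG4B, an autophagy protease gene, and CDH6, a cadherin gene, whose peaks at chr2:241652890-241653184 and chr5:31267478-31267692 had −log10 p of 5.94 and 5.90 and an adjusted p of 0.166 each in the authors' deposited table. RYK, a receptor of Wnt ligands, had 5.12, and FBXW8, CYSLTR2 and ELP2 had 5.04 each in the authors' deposited table. For 41 of the 49 peaks, the position was over 1 kb from either end of the coding gene, as for CREBBP, and 8 lay within 1 kb of an end. The promoter class comes from the assigned transcript, which need not be one of the coding gene: the RYK peak, 13577 bp inside RYK, was assigned to the pseudogene HMGB3P14, and the CDH6 and FBXW8 peaks were assigned to ENSG00000254138 and ENSG00000277840, which have no symbol here. RIC3 was 1 of those 8, with a peak at chr11:8169013-8169297 that covers an end of the gene and had a −log10 p of 4.79 in the authors' deposited table. The leukotriene receptor gene CYSLTR2 was another, with its peak 323 bp inside the gene. ATG4B, CDH6, RYK, FBXW8, CYSLTR2, ELP2 and RIC3 were chosen after their values were seen.

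Measured from the peak's middle, 61 of the 870 peaks (7.01%, 5.41 to 8.92) lay within 1 kb of the start of the assigned transcript. The median distance was 17894 bp (interquartile range 6084 to 46861), and 104 peaks were over 100 kb away.

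Peaks were not more frequent at the ends of coding genes than random positions on the same chromosomes. Within 1 kb of an end of a coding gene, 2.08% of the 864 peaks were found against 2.35% of random positions (central 95% range 1.39 to 3.36, permutation p = 0.70, adjusted p = 0.80). Coding gene bodies held 37.8% of the peaks against 42.3% of random positions (39.0 to 45.5, permutation p = 0.014), which did not pass adjustment (adjusted p = 0.11). The share in coding gene bodies passed for the 451 chromosomal peaks at or above the median −log10 p (35.9% against 41.9%, adjusted permutation p = 0.032). With peaks within 2 Mb of the largest gene-free stretch left out, it was 40.0% against 42.3% of random positions on whole chromosomes (adjusted permutation p = 0.84) and against 45.4% when random positions were kept out of the same regions (adjusted permutation p = 0.014), settings chosen after the data were seen.

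The 22 chromosomal peaks with an adjusted p under 0.05 lay mostly outside genes. CREBBP was the only coding gene body with such a peak, 4.55% against 40.2% of random positions (permutation p = 0.002, the smallest 1000 placements can give). Of the 22 peaks, 11 (50%) lay within 2 Mb of the largest gene-free stretch of their chromosome against 9.55% of random positions (permutation p = 0.002, again the smallest possible). All 11 lay inside the stretch itself: 4 peaks on chromosome 4, 3 on chromosome 17, 2 on chromosome 10 and 1 each on chromosomes 11 and 16. A stretch without genes cannot hold a peak in a gene body, so the low share in gene bodies and the high share near the stretch overlap. Placement away from the stretch was not run for the 22 peaks. Among the other 842 peaks, 52 (6.18%) lay near such a stretch (odds ratio 15.1, 95% interval 5.64 to 40.4, Fisher's exact test, two-sided, p = 4.89e-08). Some of the 11 are close neighbours, such as chr4:49710624-49710957 and chr4:49711389-49711795. Both tests count each peak as independent, so the p-values and the interval may overstate the evidence. Of all 864 chromosomal peaks, 7.29% lay near the stretch against 8.51% of random positions on whole chromosomes (adjusted permutation p = 0.45). With random positions kept out of the stretch the comparison was 7.29% against 3.08% (adjusted permutation p = 0.0053). That excess is in part built in, because peaks inside the stretch were counted and random positions could not fall there. Random positions on whole chromosomes can fall in assembly gaps, which tilts the other comparison the opposite way. Neither comparison settles whether peaks as a whole crowd there. The set of 22 peaks and the gene-free stretches were chosen after the peak list was seen.

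**Figure D2:**
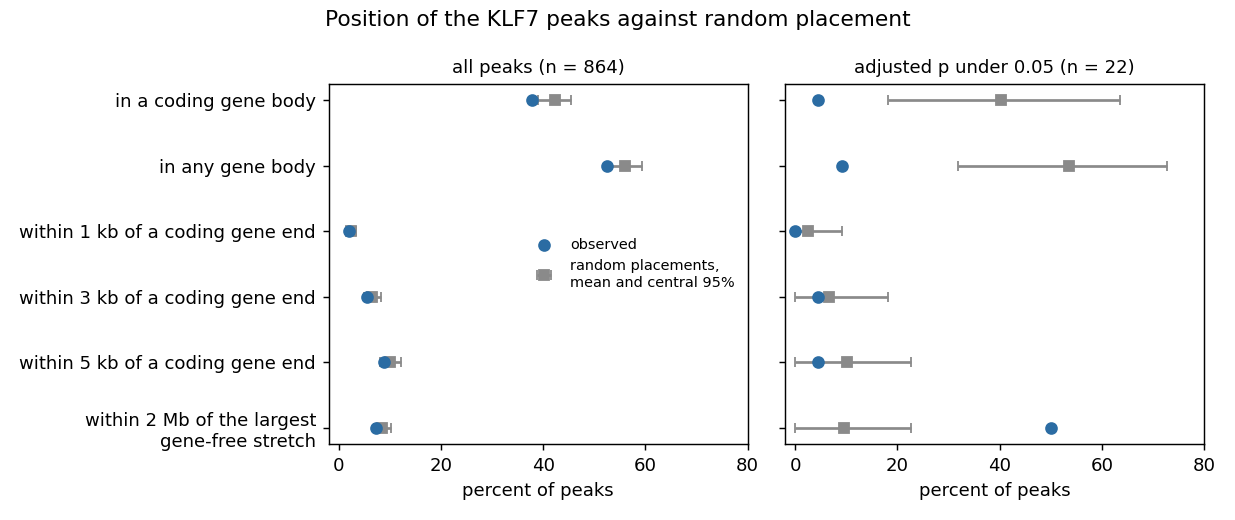
Percent of peaks (x axis) in each position relative to genes (y axis), for the 864 chromosomal peaks (left) and the 22 with an adjusted p under 0.05 (right). Blue points are observed shares and grey squares with bars are the mean and central 95% range of 1000 random placements. At right, 4.55% lie in a coding gene body and 50% near the largest gene-free stretch.

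None of the listed keratinocyte genes had a peak in the gene or within 3 kb of it. A peak lay in or within 3 kb of 342 of 20033 coding genes (1.71%). The lists of basal keratinocyte genes, epidermal differentiation genes, keratinocyte transcription factors, desmosome and tight junction genes, and keratinocyte cytokine genes hold 184 genes together. With 0 of the 184 at a peak, 3.14 were expected (Fisher's exact test, two-sided, p = 0.080), which allows a share of up to 1.98% (exact 95% limit). The difference from the background was therefore not detectable with this number of peaks. SPRR3, a cornified envelope gene, gained a peak when the flank was 10 kb and when assigned transcripts were matched by a shared end, as 1 of the 51 epidermal differentiation genes in both.

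KLF7 itself (chr2:207074137-207173851) had no peak, and the only member of the KLF and SP family with one was KLF12, which encodes a transcriptional repressor. Its peak at chr13:73795131-73795345 is in intron 4 of 6 and had a −log10 p of 3.72 in the authors' deposited table. Among 18 genes linked to KLF7 in other tissues, NTRK2, which encodes the receptor of brain-derived neurotrophic factor, had a peak in intron 16 of 19 at chr9:84938617-84938831, with 2.99 in the authors' deposited table. The transcript assigned to that peak was of the pseudogene UBE2V1P10, at a distance of -220851 bp to its start. Of 25 clock genes, CSNK1E, a casein kinase gene, had a peak at chr22:38291540-38291754, with 2.47 in the authors' deposited table. Each of the KLF and SP, KLF7-linked and clock lists thus had 1 gene with a peak. Random lists matched on gene length expected 0.413, 0.269 and 0.541 (permutation p = 0.69, 0.48 and 0.85).

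Signalling lists had 3 genes with a peak. In the TGF-beta list, 2 of 29 genes had one against 0.495 expected (Fisher's exact test, two-sided, p = 0.087, adjusted p = 0.92). Random lists matched on gene length expected 0.828 (permutation p = 0.40). The receptor gene TGFBR1 had it in intron 3 of 8 at chr9:99137258-99137482, with a −log10 p of 4.22, and the ubiquitin ligase gene SMURF1 had one 2090 bp outside the gene at chr7:99025136-99025350, with 2.79 in the authors' deposited table. The SMURF1 peak is annotated as intron 22 of 26 of another gene, ENSG00000196367, and without the flank the list had 1 gene with a peak. WNT5B was the only 1 of 46 Wnt pathway genes, with a peak classed as promoter at chr12:1633093-1633407, 1778 bp from the assigned start, and 2.65 in the authors' deposited table. That start is internal to the gene, since the peak lies 13805 bp from the nearer end of WNT5B. In the list of neuron genes, which stands for another cell type, the synaptic vesicle gene SYT1 had a peak in intron 4 of 11 at chr12:79087092-79087398, with 3.37 in the authors' deposited table. The peaks of the list members named here all had an adjusted p of 1 in the authors' deposited table.

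No list passed the test. The smallest adjusted p over 21 lists was 0.92 (Fisher's exact test), 0 lists had an unadjusted p under 0.05, and 15 lists had no gene with a peak. Besides the 5 keratinocyte lists, these were the cell cycle, epithelial-mesenchymal transition, EGF receptor and MAP kinase, ribosomal protein, oxidative phosphorylation, lipid synthesis and histone genes and the liver, blood cell, and fibroblast and melanocyte lists. The 76 ribosomal protein genes were the largest of them, with 1.30 expected and 0.213 in random lists matched on gene length. When genes were named by assigned transcripts sharing an end, 2 listed genes had a peak, SPRR3 and GAP43, a neuronal growth gene of the list linked to KLF7, and none of KLF12, NTRK2, CSNK1E, TGFBR1, SMURF1, WNT5B and SYT1 did. That matching named only 382 of the 870 rows, so a gene missing from it need not have been assigned elsewhere. The SYT1 peak was assigned to ENSG00000067715, the gene whose intron holds it.

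The 5 gene identifiers with the most peaks were 3 pseudogenes and 2 genes without a symbol here, and 4 of them had a peak in or near a gene-free stretch. More than 1 peak was given to 38 of 826 gene identifiers, and 5 had at least 3. ENSG00000233918 on chromosome 7 had 4, between positions 60310797 and 61699582. The pseudogenes SNX18P25 on chromosome 4, RPS6P15 on chromosome 10 and LOC100422478 on chromosome 17, and ENSG00000283023 on chromosome 22, had 3 each. For SNX18P25 these include the pair of strongest peaks of the list, up to 1088122 bp from the pseudogene's start in the authors' deposited table. RPS6P15 was the only one of the 5 with no peak within 2 Mb of the largest gene-free stretch.

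Chromosomes 7, 8 and 10 held more peaks, and chromosomes 6, 21 and X fewer, than expected by either coding gene number or length. HaCaT is an aneuploid line, so the comparison asks how evenly peaks fall over chromosomes. Neither expectation is adjusted for copy number, including that of X and Y, so a low or high count need not reflect binding. Chromosome 7 had 76 peaks against 40.5 expected by gene number (exact binomial test, adjusted p = 1.69e-06) and 44.6 by length (adjusted p = 7.79e-05). Chromosome 8 had 65 against 30.8 and 40.6, and chromosome 10 had 54 against 31.7 and 37.4. Chromosome X had 10 against 36.6 by gene number (exact binomial test, adjusted p = 1.69e-06) and 43.7 by length (adjusted p = 1.97e-08). Chromosome 6 had 22 against 45.2 and 47.8, and chromosome 21 had 3 against 10.3 and 13.1. Chromosome 19, dense in genes, had 11 peaks against 62.6 by gene number (exact binomial test, adjusted p = 1.25e-14) and 16.4 by length (adjusted p = 0.338).

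Of the 24 chromosomes, 14 differed from the expectation by gene number at an adjusted p under 0.05 (exact binomial test), 8 of them above and 6 below it, and 11 differed from that by length, 4 above and 7 below. With the 451 chromosomal peaks at or above the median −log10 p, 9 chromosomes passed for gene number and 1 for length, chromosome X, the only 1 to pass both. By length the adjusted p was then 0.129 for chromosome 7, 0.173 for 8, 0.289 for 10, 0.062 for 6 and 0.206 for 21, and by gene number 10, 6 and 21 did not pass either (0.056, 0.056 and 0.303).

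**Figure D3:**
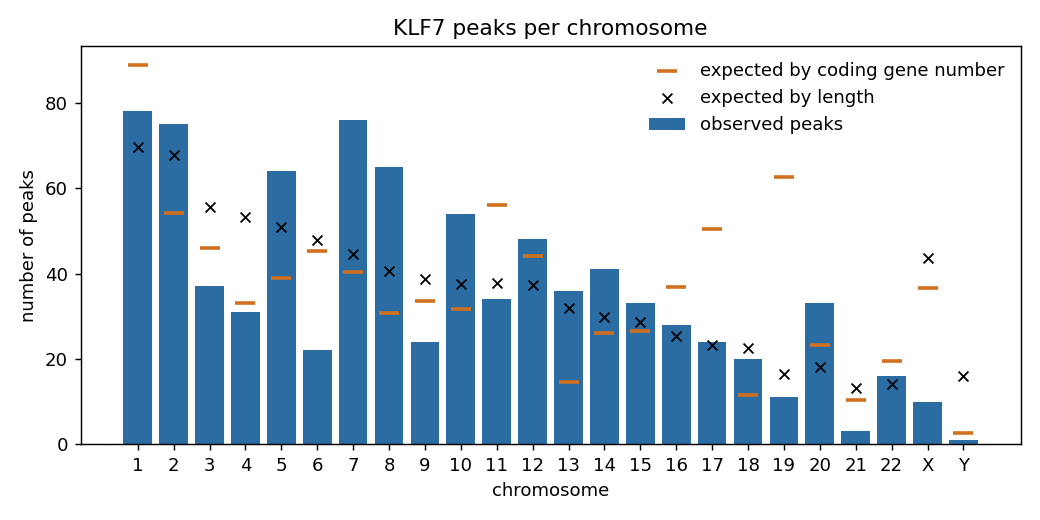
Number of peaks (y axis) per chromosome (x axis). Bars are observed counts, orange dashes the expectation by coding gene number and crosses that by length. Chromosome 7 has 76 peaks against 40.5 and 44.6, and chromosome X 10 against 36.6 and 43.7.

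Peak density also differed between the sides of some chromosomes, split at the largest gene-free stretch, a comparison added after the counts per chromosome were seen. On chromosome 3, 2 peaks lay in the 91.5 Mb before the stretch and 33 in the 104.4 Mb after it (exact binomial test, adjusted p = 2.73e-06 over 17 chromosomes). On chromosome 6, 17 lay in the 58.1 Mb before and 5 in the 110.5 Mb after it (exact binomial test, adjusted p = 0.000432). Chromosomes 2, 5 and 17 were denser before the stretch, with 0.446 against 0.216, 0.569 against 0.282 and 0.484 against 0.160 peaks per Mb (exact binomial test, adjusted p = 0.0136, 0.0375 and 0.0457). Chromosomes 4 and 9 had 3 against 24 and 5 against 19 peaks, which did not pass (exact binomial test, adjusted p = 0.230 and 0.300).

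**Figure D4:**
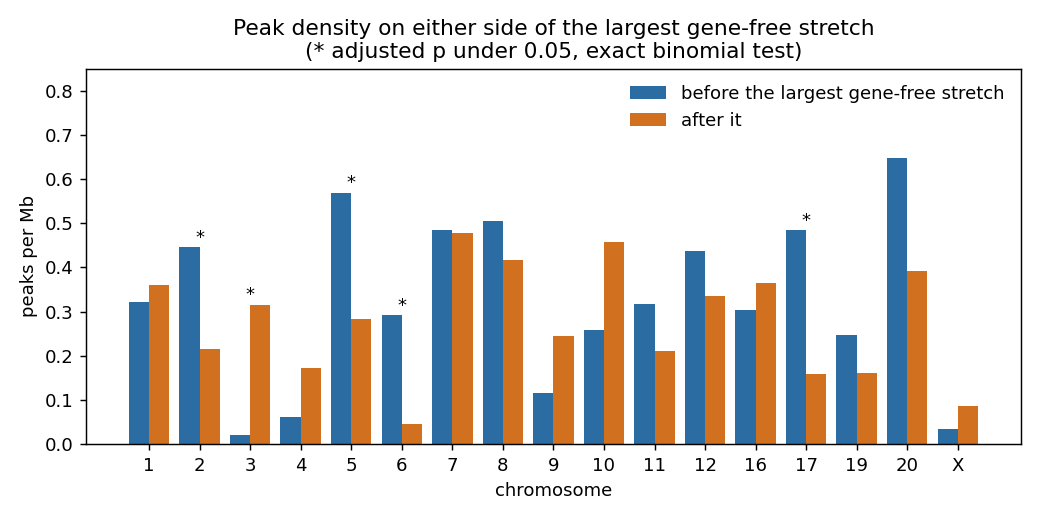
Peaks per Mb (y axis) before and after the largest gene-free stretch of each chromosome with at least 20 Mb on both sides (x axis). Asterisks mark an adjusted p under 0.05 in an exact binomial test. Chromosome 3 has 0.0219 before and 0.316 after, and chromosome 6 has 0.292 before and 0.0453 after.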

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

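The sets of peaks with an adjusted p under 0.05, without peaks near the gene-free stretch, with random placement outside that stretch, with both left out there, the 455 peaks of smaller p-values in the distance comparisons, and the flank and transcript-matching settings of the gene lists were chosen after seeing the data. Under other settings, 31 values stayed with the main value, 9 moved, 4 passed a threshold that the main value did not and 0 reversed. The 31 include settings that merge overlapping peaks or count each region once. Those could not change a value, because 0 peaks overlap or touch another. The 21 gene lists gave 0 calls under all 7 other settings, with smallest adjusted p from 0.315 to 1, and the background of all genes with a symbol gave 2 lists at an unadjusted p under 0.05.

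Keeping the peaks at or above the median −log10 p left 455 peaks (451 on chromosomes), 9 chromosomes past the threshold by gene number and 19 gene identifiers with several peaks, against 870, 14 and 38. Fewer peaks enter each of these counts by construction. The share in coding gene bodies was then 35.9% (adjusted permutation p = 0.032), and it was 37.8% against 44.9% (adjusted permutation p = 0.0053) when random positions alone avoided the gene-free stretch, which lowers the observed share relative to random by construction. Leaving out only peaks near the stretch tilts it the other way (40.0% against 42.3%, adjusted permutation p = 0.84), and leaving out both peaks and random positions there gave 40.0% against 45.4% (adjusted permutation p = 0.014). With only peaks of adjusted p under 0.05 it was 4.55% (adjusted permutation p = 0.0053), promoters held 26.1%, introns 0% and distal intergenic regions 73.9%; the cause was not tested. Windows of 500 bp, 2 kb and 5 kb around assigned starts held 4.02%, 12.1% and 21.1%, as their sizes require. The fold enrichment threshold, the mean enrichment over a gene's peaks and all motif alternatives were not run, since the table analysed gives no fold and no sequence was used here. No paired analysis was possible because each group has 1 library. Counts of reads per peak, which would show what depth limits, are not given in the table analysed.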

Other observations

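The tests of strong peaks against the rest, of their promoter share and input background and of p-values as Poisson tails, the use of the planned test by gene number against a proportional peak number, and the list of coding genes with several peaks, were chosen only after the results were seen.

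The 20 coding genes with several peaks ranged from CES3 (13.9 kb) to RBFOX1 and had a median length of 489 kb, inside the 301 to 912 kb of 100 random placements, which gave 12 to 27.5 such genes. RBFOX1, a splicing regulator gene of 2474 kb, had 3 peaks on chromosome 16, at positions 5369545, 6842818 and 7025802, with −log10 p of 4.20, 2.65 and 3.40 in the authors' deposited table. The other 19 had 2 peaks each, among them LRP1B (1900 kb), DAB1 (1552 kb), SGCZ (1154 kb), DPP6 (1146 kb), CTNND2 (933 kb) and GRM8 (814 kb). All 342 coding genes with a peak had a median length of 157.5 kb against 23.6 kb for other coding genes. In the random placements that median was 144 kb (central 95% range 124 to 172), and the observed length was inside that range. The number of genes with a peak, 342, was below the 388 of random placements (360 to 417).

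Peaks with an adjusted p under 0.05 lay in or within 2 Mb of the largest gene-free stretch of their chromosome more often than the rest. The odds ratio was 15.1 (Fisher's exact test, two-sided, p = 4.89e-08, neighbouring peaks counted as independent). Whether promoter binding by KLF7 gave most of these strong peaks is not settled. Of the 23, 17 were distal intergenic and 26.1% were in promoters (exact 95% interval 10.2 to 48.4), so most were not classed as promoter. The upper limit falls only just short of a majority, a cut set after the results were seen. The interval also counts close neighbours as independent, such as chr4:189233811-189234125 and chr4:189234992-189235246. Whether promoters were more frequent among the strong peaks than among the rest stays open (odds ratio 1.93, 95% interval 0.611 to 5.24, Fisher's exact test, two-sided, p = 0.239), and binding of KLF7 to repeats was not tested. A pile-up in or beside centromeres of reads from repeat copies missing from the assembly, in the input too, also stays open. With p-values read as Poisson tails, as in the last paragraph, 7 of the 11 strong peaks near a stretch and 1 of the 11 others had no match at an input background of 5 fragments or less (odds ratio 15.0, 95% interval 1.30 to 865, Fisher's exact test, two-sided, p = 0.0237). No match or a background above the constant one was found for 9 and 7 (odds ratio 2.46, 95% interval 0.260 to 34.9, Fisher's exact test, two-sided, p = 0.64). That split had little room to separate the groups, since only 251 of all 854 matched peaks had the constant background. The weaker peaks without a match lay in or near a stretch too, apart from the one at chr21:7962951. Both splits were picked with the counts in view, a missing match is only an indirect sign of a high input, no repeat or mappability value was used, and whether the explanation covers the CREBBP peak and 10 other chromosomal ones outside the 2 Mb was not tested, since the largest gene-free stretch need not be the centromere, as on chromosome Y.

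Peaks were spread unevenly over chromosomes. A peak number proportional to the number of coding genes is argued against by the 14 of 24 chromosomes that differed from that expectation (exact binomial test), while a looser relation to gene density stays open (Spearman's rho 0.0559 over 22 autosomes, permutation p = 0.80, adjusted 0.80, Pearson's r -0.110, permutation p = 0.63, and 0.201 without chromosomes 17 and 19). Chromosome-wide differences in DNA amount, as in an aneuploid line, may contribute, since peaks in genes and intergenic peaks per Mb varied together (rho 0.612, permutation p = 0.0034, adjusted 0.010 over 3 relations, r 0.609, permutation p = 0.0028, and 0.557 without chromosomes 20 and 21), which other chromosome-wide factors could also give. More input DNA on the chromosomes with more peaks, read from the share of peaks with a raised local background, could not be decided (rho 0.0883 over 21 autosomes, permutation p = 0.70, adjusted 0.80, r 0.284, permutation p = 0.21, and -0.0322 without chromosomes 6 and 20). DNA amount on single chromosome sides, such as the side of chromosome 3 with 2 peaks, was not tested.

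Many peaks share the same p-value, and the 870 peaks take only 181 distinct ones. A candidate explanation is that each p is the Poisson tail of a whole number of overlapping fragments over a background counted in the input. A grid of whole counts and backgrounds up to 5 matched 98.2% of the peaks within 1.2e-05, against at most 1.15% in 20 runs with randomly shifted values. Its backgrounds were a constant of 1.30 fragments or input counts in 10 kb, 1 kb or a fragment length of 215 bp. That constant was itself solved from the 2 most common p-values of the list and serves 251 peaks. Of the 16 unmatched peaks, 8 had an adjusted p under 0.05, 4 of them the chromosome 4 peaks in the gene-free stretch. All 16 except those at chr21:7962951 and chrY:11305291 lay in or within 2 Mb of the largest gene-free stretch. Of the 864 chromosomal peaks, 7.29% did. This difference was not tested. With p-values read as such tails, the median peak would rest on 7 fragments (interquartile range 6 to 8), 87.6% of the 854 matched peaks on 8 or fewer, and the CREBBP peak on 20 over a background of 1.57. The peak caller is not given in the sources used here, the table lists no fragment count to set beside these values, and no biological explanation was tested.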
